A study of Mus musculus with 12 samples.

How the data were processed

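In all, 12 bulk RNA-seq libraries of mouse OT-I CD8 T cells were analysed, 3 in each of 4 groups. OT-I cells carry a transgenic T cell receptor for a peptide of ovalbumin. Per the labels, naive cells came from lymph nodes of OT-I mice without tumours, and effector cells from an in vitro culture with antigen of 5 days. The other libraries came from CD44-positive OT-I cells that were sorted out of B78ChOVA tumours 4 or 14 days after transfer into C57BL/6J mice. B78ChOVA is a melanoma line that carries mCherry and ovalbumin. The sort went into lysis buffer, RNA was taken on oligo(dT) beads, and cDNA was amplified before transposase-based library preparation, per the labels' protocols. They also state that a shallow sequencing run came first and that libraries with few coding reads were not sequenced further.

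The deposited values are counts of reads per gene. Per the submitters' processing notes, reads were handled with fastp 0.19.6 and STAR 2.6.1b and the genome build was GRCm38. The counting options and the annotation release are not given in the sources used here. Each deposited table of counts has an unstranded column and a column for each strand, and between 49.8% and 49.9% of the stranded gene counts fell on the sense column. The unstranded counts were used for that reason, so reads of a gene and of an overlapping or antisense gene cannot be told apart. The 4 summary lines of each table were left out of library sizes. As shares of all reads in a table, 20.7% to 30.2% lay outside genes, 4.90% to 5.52% did not map, 5.90% to 7.29% mapped to several places and 3.22% to 3.81% were ambiguous between genes. Reads that map to several places were not counted for any gene, so counts of near-identical copies are uncertain. This holds for ribosomal protein genes, Hspa1a and Hspa1b, haemoglobin genes, Klr and Klra receptors, Lilr4b, Ifit and Oas genes, class II MHC genes and T cell receptor V segments. Of 55401 gene identifiers, 55141 matched the GENCODE M21 annotation of GRCm38 by identifier without its version, and 260 did not. Symbols and gene spans were taken from that annotation. No unique molecular identifiers are described in the labels, so intervals and floors cover counting error only.

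Counts were filtered with filterByExpr, which left 16426 genes, and scaled with TMM factors in edgeR 4.0.16 (R 4.3.3). Levels are mean ± SD of CPM, counts scaled to a common library total with TMM factors, over the 3 libraries of a group, computed here from the deposited counts. All 12 libraries entered 1 quasi-likelihood fit with robust dispersion (8 residual degrees of freedom). Contrasts between groups gave log2 fold changes with their SE, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05. There were 3 main contrasts (effector versus naive, day 14 versus effector, day 14 versus day 4) and 3 further ones. A test across the 4 groups and the genes higher, or lower, in both tumour groups than in both other groups completed the set. A fold against a group without a count used a floor of 3 counts over the group and is written as at least that fold. With 1 to 3 counts in a group the ratio has a 95% interval from the counts. Shares of receptor segments have Wilson 95% intervals.

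Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over 18 function lists and 6 contrasts (108 tests). Camera with an estimated correlation and fry were run beside it. The 18 function lists were inhibitory receptors, exhaustion-associated transcription factors, naive and stem-like T cell genes, cytotoxic effector genes, myeloid-attracting and myeloid growth factors, costimulatory receptors, chemokine receptors, tissue residency genes, DNA replication, mitosis, glycolysis, hypoxia response, oxidative phosphorylation, cholesterol synthesis, type I interferon response, immediate early and stress genes, the unfolded protein response and cytosolic ribosomal proteins. The 10 marker lists stood for macrophages and monocytes, dendritic cells and MHC class II, B cells, melanoma, fibroblasts, endothelium, NK cells, CD4 T cells and Tregs, neutrophils and erythroid cells, and formed a separate family of 54 tests over the 9 lists with tested genes.

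The groups, tests, gene lists, listed alternatives and the rule for named genes were chosen before the data were examined. The rule took protein-coding genes that were called, had a mean log2 CPM of at least 4 and did not overlap between the groups. It named the 5 with the highest and the 5 with the lowest log2 fold change in each main contrast and 2 each in the further ones. It also took up to 3 called members per function list described, the most abundant member of each marker list, 8 higher and 4 lower genes for the intersection, and a fixed panel of 16 genes. Genes named as the few members of a list that were called, or that moved against the rest of it, and those of the opposite effects at day 4 and day 14, were chosen after their values were seen. Some genes that the rule took are not reported here, while counts over lists and over all genes include them.

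The alternatives were other scalings (RLE, upper quartile, total counts), DESeq2 1.42.0, no filter on low counts, a filter of 50 counts in 3 libraries, protein-coding genes without mitochondrial genes, fits of the compared groups alone, the replicate number as a block, and each library left out in turn. A subtraction of transcripts that moved with melanoma markers was added after seeing the data. In it, the slope of a gene's CPM on the summed CPM of the melanoma markers within the tumour groups, times that sum, was taken off each tumour library before the fit. The pipeline was tested in 3 simulations of effector versus naive (16426 genes). It called 22.4% of 201 genes changed 1.5-fold, 50.2% of 201 changed 2-fold and 73.2% of 198 changed 4-fold. False calls were 4.59% of all calls. The data had far more calls, so these shares may differ. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Figures and summaries were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.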

Results

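The libraries measured poly(A) transcripts of OT-I CD8 T cells in 4 states, with 3 libraries each: naive, effector after culture with antigen, and tumour-infiltrating cells taken at day 4 or day 14, which the labels call exhausted. The series concerns tumour macrophages and exhausted CD8 T cells. Its tables hold gene counts for naive, activated and tumour-infiltrating cells, so the contrasts ask how transcript levels differ between these states. Gene counts per library ranged from 11937053 to 17094006. Means were 12463516 ± 460720 in naive, 13484719 ± 1185541 in effector, 14964599 ± 1248099 in day 4 and 16355700 ± 1062584 in day 14 libraries (SD, n = 3 each). Errors of levels are SDs and errors of log2 fold changes are SEs throughout.

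Among T cell receptor segments, Trbv12-1 and Trbv12-2 (V beta 5) held 95.5% to 98.8% of the 1048 to 5387 counts over Trbv segments in each library (Wilson 95% interval bounds from 94.5% to 99.1%). Trav14 segments (V alpha 2) held 4.28% to 13.05% of the 730 to 1957 counts over Trav segments. Trav14 has several near-identical copies and multimapping reads were not counted, so that share is uncertain. Libraries of a group correlated with Pearson r of 0.981 to 0.989 across genes and libraries of different groups with 0.812 to 0.977, and genes are not independent replicates. The principal component with the most variance (71.8%) separated tumour from other libraries. By edgeR, 12283 of 16426 genes differed among the 4 groups, and DESeq2 called 13080.

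**Figure D1:**
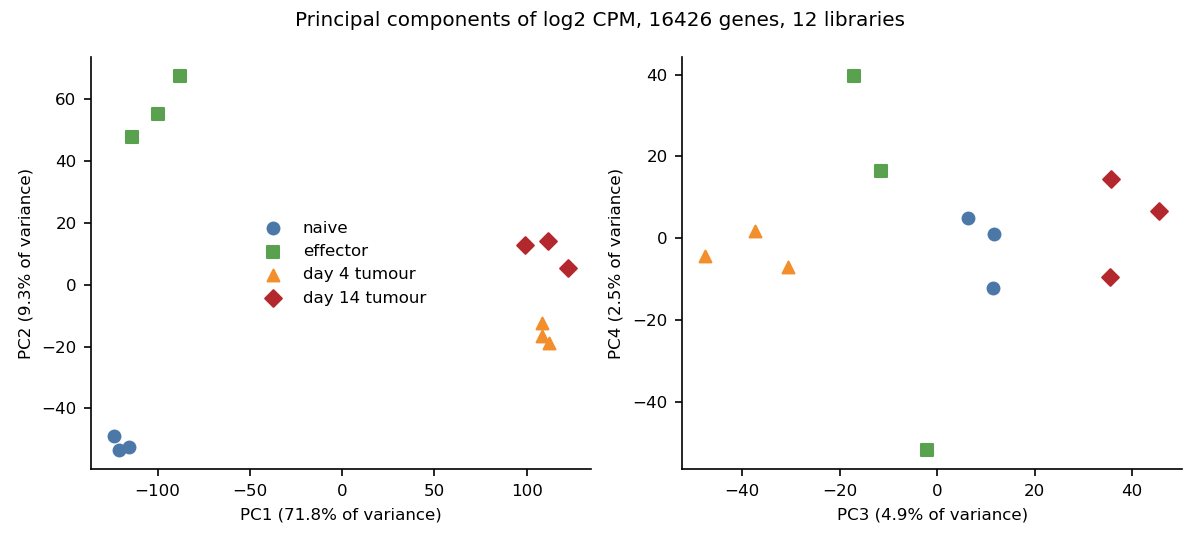
Scores of the 12 libraries on principal components 1 (71.8% of variance) and 2 (9.33%), left, and 3 (4.87%) and 4 (2.51%), right, of log2 CPM over the 16426 tested genes, with 1 point per library and a colour and shape per group. The 6 tumour libraries lie apart from the 6 naive and effector libraries along component 1, and effector replicate 2 lies at -51.9 on component 4, apart from the other effector libraries.

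Effector cells were compared with naive cells to ask how culture with antigen changed OT-I transcripts. Ctla4 (ENSMUSG00000026011.13, chromosome 1, 60887000 to 60915832), an inhibitory receptor of activated T cells, averaged 296 ± 62.1 CPM in effector and 1.21 ± 0.434 CPM in naive libraries (244-fold higher, log2 fold change 7.93, SE 0.27, edgeR adjusted p = 4.99e-09). Ccl5 (ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518), a chemokine of activated T cells, averaged 120.5 ± 81.2 against 4.30 ± 3.31 CPM (28.1-fold, log2 fold change 4.81, SE 0.70, edgeR adjusted p = 0.00145). The receptors Cxcr3 (ENSMUSG00000050232.6, log2 fold change 4.22, SE 0.42), Slamf7 (ENSMUSG00000038179.13, log2 fold change 4.12, SE 0.43) and Il12rb2 (ENSMUSG00000018341.12, log2 fold change 3.59, SE 0.38) also rose. Ccr9 (ENSMUSG00000029530.16), a gut-homing chemokine receptor, fell from 339 ± 103 to 52 ± 41.4 CPM (log2 fold change -2.70, SE 0.60, edgeR adjusted p = 0.0121). The interferon-induced Oas2 (ENSMUSG00000032690.16, log2 fold change -5.31, SE 0.32) and Slfn5 (ENSMUSG00000054404.13, log2 fold change -4.56, SE 0.29) fell too, as did Dtx1 (ENSMUSG00000029603.15, log2 fold change -4.50, SE 0.53) and Xkrx (ENSMUSG00000031258.4, log2 fold change -3.63, SE 0.43). Ccr9 was not called in the fit of the compared groups alone (edgeR adjusted p = 0.0740), range over all alternatives 0.000250 to 0.0740. Ccl5 had a log2 fold change of 5.63 without naive replicate 2 and 4.13 without effector replicate 2. Ccr9 had a log2 fold change of -3.54 without effector replicate 1.

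Receptor lists moved upward in effector cells. Of 10 costimulatory receptors 9 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 2.43e-06, and adjusted p = 0.0672 with an estimated correlation), led by Icos (ENSMUSG00000026009.14, log2 fold change 1.93, SE 0.12), Tnfrsf9 (ENSMUSG00000028965.13, log2 fold change 1.17, SE 0.18) and Tnfrsf18 (ENSMUSG00000041954.18, log2 fold change 1.04, SE 0.15). Among 14 inhibitory receptors 6 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00239, and adjusted p = 0.170 with an estimated correlation). Beside Ctla4, Lag3 (ENSMUSG00000030124.2, log2 fold change 7.48, SE 0.67) and Tigit (ENSMUSG00000071552.5, log2 fold change 5.34, SE 0.59) had the highest fold changes there. Lag3 averaged 33.5 ± 18.7 CPM in effector libraries, and Pdcd1 (ENSMUSG00000026285.7, chromosome 1, 94038305 to 94052553), which encodes PD-1, 2.67 ± 1.19 against 0.659 ± 0.480 CPM in naive ones (log2 fold change 1.97, SE 0.47, edgeR adjusted p = 0.0109). Havcr2 (ENSMUSG00000020399.14, chromosome 11, 46454935 to 46481255), which encodes TIM-3, was not called (log2 fold change 4.19, SE 1.38, edgeR adjusted p = 0.0593). Entpd1 (ENSMUSG00000048120.16), a membrane enzyme that degrades extracellular ATP, rose (log2 fold change 3.78, SE 0.60, edgeR adjusted p = 0.000949). Btla (ENSMUSG00000052013.15, log2 fold change -1.58, SE 0.18), another inhibitory receptor, fell. Of 11 chemokine receptors 6 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.0183, and adjusted p = 0.164 with an estimated correlation). The inflammatory receptor Ccr2 (ENSMUSG00000049103.14, log2 fold change 5.82, SE 0.76) was among the highest with Cxcr3. Havcr2 was called without effector replicate 1 or 3 (edgeR adjusted p = 0.0428 and 0.0332) and by DESeq2 (DESeq2 adjusted p = 4.27e-05), range over all alternatives 4.27e-05 to 0.297. Havcr2 and Ccr2 had log2 fold changes of 1.94 and 5.12 without effector replicate 2. Lag3 had a log2 fold change of 8.09 without naive replicate 3. Pdcd1 had a log2 fold change of 2.59 without naive replicate 1.

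Part of the metabolic genes rose in effector cells. Of 17 glycolysis genes 12 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 2.43e-06, and adjusted p = 0.208 with an estimated correlation), with hexokinase Hk2 (ENSMUSG00000000628.10, log2 fold change 2.66, SE 0.32), the glucose transporter Slc2a3 (ENSMUSG00000003153.10, log2 fold change 1.89, SE 0.13) and the lactate transporter Slc16a3 (ENSMUSG00000025161.16, log2 fold change 2.28, SE 0.39) at the top. Of 16 hypoxia response genes 8 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.000250, and adjusted p = 0.216 with an estimated correlation). The members Bhlhe40 (ENSMUSG00000030103.11, log2 fold change 4.49, SE 0.34), Vegfa (ENSMUSG00000023951.18, log2 fold change 3.13, SE 0.76) and Egln3 (ENSMUSG00000035105.5, log2 fold change 2.81, SE 0.25) led, and Bhlhe40 is a transcription factor that also stands in the exhaustion-associated list. In that list of 15, 7 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0248, and adjusted p = 0.247 with an estimated correlation). The factors Irf4 (ENSMUSG00000021356.10, log2 fold change 2.72, SE 0.37) and Nr4a1 (ENSMUSG00000023034.7, log2 fold change -2.06, SE 0.31), both induced by receptor signals, had the largest changes beside Bhlhe40. Tox (ENSMUSG00000041272.11, chromosome 4, 6686353 to 6991557), a factor of exhausted cells, fell (log2 fold change -1.45, SE 0.12, edgeR adjusted p = 6.48e-07). Vegfa was not called without naive replicate 1 (edgeR adjusted p = 0.0557) or after the melanoma subtraction, which left its counts in both groups as they were and raised its SE (log2 fold change 3.11, SE 1.20, edgeR adjusted p = 0.0848), range over all alternatives 0.000259 to 0.0848. Irf4 had a log2 fold change of 3.42 without naive replicate 2. Vegfa had a log2 fold change of 2.18 without effector replicate 3.

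Part of the cytotoxic genes rose in effector cells, and cell cycle lists were not called. Gzmb (ENSMUSG00000015437.5), which encodes granzyme B, averaged 77.5 ± 97.4 CPM in effector against 1.09 ± 0.410 CPM in naive libraries and rose (log2 fold change 6.12, SE 1.24, edgeR adjusted p = 0.00828), and replicate 2 held 189 CPM. Of 18 cytotoxic genes 9 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0217, and adjusted p = 0.424 with an estimated correlation), with Fasl (ENSMUSG00000000817.10, log2 fold change 5.87, SE 0.70) and Gzmk (ENSMUSG00000042385.14, 108-fold higher by counts, 95% interval 18.9 to 4302) among the highest. Prf1 (ENSMUSG00000037202.6, log2 fold change -1.88, SE 0.26), which encodes perforin, fell. Mki67 (ENSMUSG00000031004.8), a marker of cycling cells, averaged 228 ± 305 CPM, with 579.6 CPM in effector replicate 2, and was not called (log2 fold change 1.41, SE 0.94, edgeR adjusted p = 0.324). Of 20 mitosis genes 1 rose and 0 fell (0 and 0 adjusted over the list alone), the 1 being Ccnb1 (ENSMUSG00000041431.16, log2 fold change 2.37, SE 0.71), and of 19 DNA replication genes 6 rose and 1 fell (7 and 1 adjusted over the list alone). Ifng (ENSMUSG00000055170.4) was not called (log2 fold change 0.83, SE 1.01, edgeR adjusted p = 0.601). Gzmb was not called after the melanoma subtraction, which left its counts in both groups as they were and raised its SE (log2 fold change 6.12, SE 2.34, edgeR adjusted p = 0.0929) or in the fit of the compared groups alone (edgeR adjusted p = 0.0617), range over all alternatives 0.00187 to 0.0929. Gzmk was not called without naive replicate 1, 2 or 3 (edgeR adjusted p = 0.0922, 0.0725 and 0.0714), range over all alternatives 2.53e-05 to 0.0922. Prf1 was not called after the melanoma subtraction, which left its counts in both groups as they were and raised its SE (log2 fold change -1.89, SE 1.05, edgeR adjusted p = 0.235), range over all alternatives 5.72e-16 to 0.235. Ccnb1 was not called without naive replicate 1, 2 or 3, day 4 replicate 1, 2 or 3 or day 14 replicate 1, 2 or 3 (edgeR adjusted p = 0.0579 to 0.116), with total counts as scaling (edgeR adjusted p = 0.05004), with no filter on low counts (edgeR adjusted p = 0.0827) or in the fit of the compared groups alone (edgeR adjusted p = 0.0920), range over all alternatives 0.00299 to 0.116. Gzmb, Mki67 and Ccnb1 had log2 fold changes of 4.28, -0.72 and 1.29 without effector replicate 2. Mki67 and Ifng had log2 fold changes of 2.02 and 2.40 without naive replicate 2. Ifng had a log2 fold change of 1.42 without effector replicate 1. Gzmk was by counts 71.9-fold (95% interval 12.6 to 2866) higher without naive replicate 3, 40.9-fold (6.75 to 1670) without effector replicate 2 and at least 23.5-fold without naive replicate 1.

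Interferon response and ribosomal protein genes moved downward. Of 20 type I interferon genes 0 rose and 8 fell (2 and 12 adjusted over the list alone, camera adjusted p = 0.000705, and adjusted p = 0.428 with an estimated correlation), with Oasl2 (ENSMUSG00000029561.17, log2 fold change -5.22, SE 0.68), Isg15 (ENSMUSG00000035692.7, log2 fold change -2.28, SE 0.29) and Usp18 (ENSMUSG00000030107.10, log2 fold change -2.04, SE 0.22) changing most. Of 22 ribosomal protein genes 1 rose and 11 fell (1 and 14 adjusted over the list alone, camera adjusted p = 0.000218, and adjusted p = 0.428 with an estimated correlation), with small changes such as those of Rpl5 (ENSMUSG00000058558.12, log2 fold change -0.56, SE 0.10) and Rpl14 (ENSMUSG00000025794.9, log2 fold change -0.54, SE 0.11). Of 18 naive and stem-like genes 2 rose and 4 fell (3 and 4 adjusted over the list alone). The median of that list was near 0 and its sign depended on the scaling. Tcf7 (ENSMUSG00000000782.16), which encodes TCF-1, was not called (log2 fold change 0.59, SE 0.31, edgeR adjusted p = 0.214), and Il7r (ENSMUSG00000003882.5) was not called (log2 fold change 0.63, SE 0.38, edgeR adjusted p = 0.281). Tcf7 was called without day 14 replicate 3 (edgeR adjusted p = 9.75e-05) and in the fit of the compared groups alone (edgeR adjusted p = 0.000264), range over all alternatives 9.75e-05 to 0.416. Oasl2 had a log2 fold change of -6.99 without effector replicate 2.

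The lists not called for this contrast were myeloid-attracting factors (3 rose and 1 fell of 15), tissue residency (5 rose and 4 fell of 12), oxidative phosphorylation (5 rose and 1 fell of 21), cholesterol synthesis (4 rose and 2 fell of 20), the unfolded protein response (4 rose and 1 fell of 14) and immediate early genes (1 rose and 3 fell of 16), beside mitosis, replication and naive genes. With total counts as scaling, oxidative phosphorylation and cholesterol genes had more falls (4 and 3) than rises (1 and 2). Of 18 macrophage markers 1 rose and 8 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.0101, and adjusted p = 0.602 with an estimated correlation). Melanoma, B cell and endothelial markers had 0 calls by edgeR. At an unadjusted p under 0.05, 0, 0 and 0 changed, and DESeq2 called 1, 0 and 0. Of the other marker lists, 2 rose and 2 fell of 7 dendritic cell markers, 0 rose and 2 fell of 8 fibroblast markers, 2 rose and 0 fell of 2 NK cell markers, 3 rose and 0 fell of 6 CD4 T cell and Treg markers and 0 rose and 2 fell of 4 erythroid markers. In all, 4098 of 16426 genes were called, 2395 higher and 1703 lower, and 1658 by at least 2-fold. With total counts as scaling the split was 1544 higher and 2508 lower, with the median of all genes shifted by -0.12. Reads outside genes made up 28.2 ± 2.21% of all reads in naive and 22 ± 0.359%, 22.4 ± 1.93% and 23.8 ± 1.26% in effector, day 4 and day 14 libraries, and this difference was not tested as a source of changes against naive cells.

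Tumour-infiltrating cells at day 14 were compared with effector cells to ask how cells called exhausted differ from cells activated in culture. Pdcd1 averaged 697 ± 55.6 CPM at day 14 and 2.67 ± 1.19 CPM in effector libraries (265-fold higher, log2 fold change 8.05, SE 0.31, edgeR adjusted p = 1.79e-09). Nr4a2 (ENSMUSG00000026826.13, log2 fold change 7.98, SE 0.28), Rgs16 (ENSMUSG00000026475.7, log2 fold change 8.04, SE 0.16) and Sema6d (ENSMUSG00000027200.17, log2 fold change 7.04, SE 0.50) rose strongly as well. Dct (ENSMUSG00000022129.4), a pigment synthesis enzyme from the melanoma marker list, had the highest rise of all genes that met the rule (675 ± 476 against 0.759 ± 0.177 CPM, log2 fold change 9.79, SE 0.79, edgeR adjusted p = 8.15e-06). Falls included those of St8sia1 (ENSMUSG00000030283.7, log2 fold change -6.13, SE 0.28), Pik3ip1 (ENSMUSG00000034614.14, log2 fold change -5.80, SE 0.17), Tnfrsf26 (ENSMUSG00000045362.8, log2 fold change -5.61, SE 0.30) and Itgae (ENSMUSG00000005947.11, log2 fold change -5.45, SE 0.64). The melanoma subtraction uses Dct and cannot test it. Dct was not called there (log2 fold change 2.36, SE 2.02, edgeR adjusted p = 0.338), range over all alternatives 5.65e-50 to 0.338. Dct had a log2 fold change of 9.09 without day 14 replicate 1.

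Inhibitory receptors and transcription factors of exhausted cells were higher at day 14. Of 14 inhibitory receptors 12 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.000430, and adjusted p = 0.164 with an estimated correlation). Havcr2 averaged 1025 ± 208 CPM at day 14 against 11.2 ± 15.4 CPM in effector libraries (log2 fold change 6.56, SE 0.96, edgeR adjusted p = 0.000382), and 29 CPM in effector replicate 2. Cd244a (ENSMUSG00000004709.14, log2 fold change 6.0, SE 0.66), Lag3 (log2 fold change 1.71, SE 0.36) and Entpd1 (log2 fold change 3.52, SE 0.41) rose beside it, while Vsir (ENSMUSG00000020101.14, log2 fold change -1.91, SE 0.11), which encodes VISTA, fell. Of 15 transcription factors 14 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 2.67e-07, and adjusted p = 0.0672 with an estimated correlation), led by Nr4a2, Nr4a3 (ENSMUSG00000028341.9, log2 fold change 6.37, SE 0.28) and Tox2 (ENSMUSG00000074607.11, at least 138-fold higher). Tox averaged 719 ± 55.8 against 40.7 ± 6.65 CPM (log2 fold change 4.15, SE 0.13, edgeR adjusted p = 9.99e-13). Melanoma markers summed to 1145 ± 807 CPM at day 14 and 42.7 ± 1.31 CPM in effector libraries. After the melanoma subtraction, 6 of 11 inhibitory receptors and 11 of 12 factors stayed higher in both tumour groups. The receptors lost were Havcr2, Lag3, Ctla4, Cd244a and Cd200r1. In this contrast Havcr2, Lag3 and Cd244a stayed called under every alternative (edgeR or DESeq2 adjusted p at most 0.0251). Havcr2 and Cd244a had log2 fold changes of 8.81 and 7.11 without effector replicate 2. Tox2 was by counts at least 87.8-fold higher without effector replicate 1 and at least 91.3-fold without effector replicate 3.

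**Figure D2:**
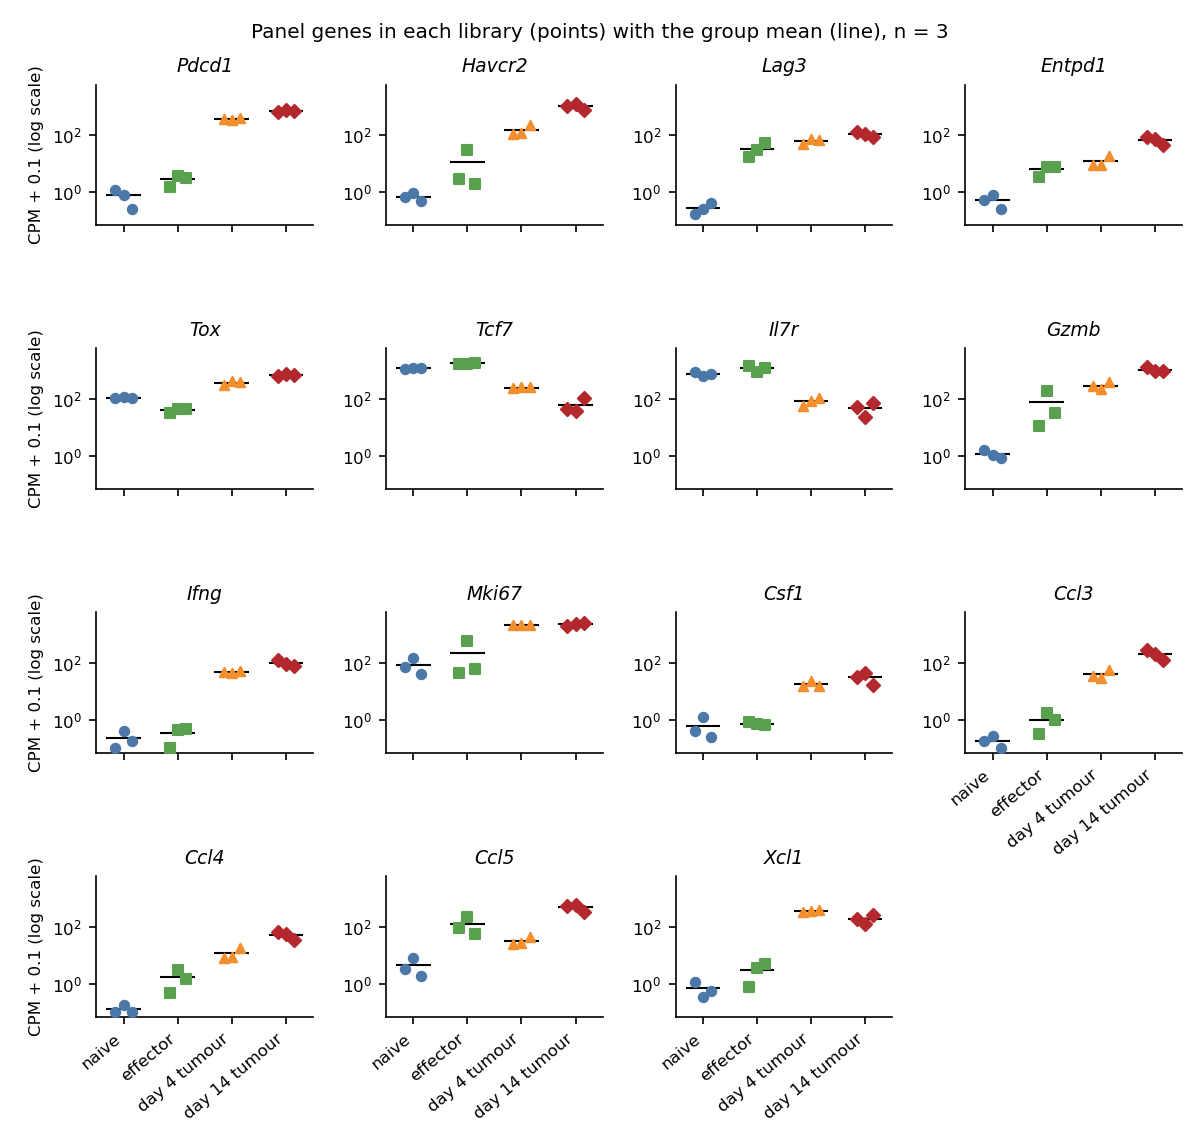
CPM plus 0.1, on a log axis, of 15 genes of the fixed panel in each group, with 1 point per library, 3 libraries per group and a line at the group mean. Pdcd1 averages 697 CPM at day 14 and 2.67 CPM in effector libraries.

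Genes of naive and stem-like cells were lower at day 14 than in effector cells. Of 18 such genes 0 rose and 17 fell (0 and 17 adjusted over the list alone, camera adjusted p = 1.57e-08, and adjusted p = 0.164 with an estimated correlation). Id3 (ENSMUSG00000007872.3, log2 fold change -5.39, SE 0.32) and Tcf7 (62.2 ± 36.5 against 1779 ± 74.1 CPM, log2 fold change -4.84, SE 0.37, edgeR adjusted p = 3.49e-06) were among the largest falls. Il7r, the receptor for a survival cytokine, fell (log2 fold change -4.61, SE 0.44, edgeR adjusted p = 2.29e-05). Of 12 tissue residency genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0264, and adjusted p = 0.217 with an estimated correlation). Rgs2 (ENSMUSG00000026360.9, log2 fold change 7.03, SE 0.26) and Rgs1 (ENSMUSG00000026358.13, log2 fold change 5.69, SE 0.23) rose, and Itgae, an integrin of epithelial resident cells, fell. Of 10 costimulatory receptors 7 rose and 2 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.0291, and adjusted p = 0.232 with an estimated correlation), with Tnfrsf9 (log2 fold change 6.07, SE 0.16), Tnfrsf4 (ENSMUSG00000029075.6, log2 fold change 4.61, SE 0.15) and Tnfrsf1b (ENSMUSG00000028599.10, log2 fold change 2.72, SE 0.14) highest, while Cd226 (ENSMUSG00000034028.16, log2 fold change -0.80, SE 0.12) and Cd27 (ENSMUSG00000030336.14, log2 fold change -0.73, SE 0.08) fell. The melanoma marker sum ranged from 513 to 2054 CPM over the 3 day 14 libraries, and the 5 costimulatory and 3 residency genes higher in both tumour groups stayed so after its subtraction. Tcf7 had a log2 fold change of -5.43 without day 14 replicate 3.

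Cytotoxic genes and secreted factors for myeloid cells were higher at day 14. Of 18 cytotoxic genes 15 rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 3.78e-05, and adjusted p = 0.209 with an estimated correlation). Ifng (log2 fold change 8.65, SE 0.42), Cx3cr1 (ENSMUSG00000052336.7, 1340-fold higher by counts, 95% interval 240.2 to 52970) and Gzmf (ENSMUSG00000015441.4, at least 32.4-fold higher) had the largest fitted changes, and Gzmb averaged 1073 ± 200.1 against 77.5 ± 97.4 CPM (log2 fold change 3.80, SE 0.90, edgeR adjusted p = 0.00605). Lamp1 (ENSMUSG00000031447.7, log2 fold change -0.46, SE 0.12) fell. Of 15 myeloid-attracting and myeloid growth factors 13 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 8.09e-05, and adjusted p = 0.164 with an estimated correlation). That list follows the theme of the series and is not independent evidence of its direction. Ccl3 (ENSMUSG00000000982.5, log2 fold change 7.89, SE 0.58), Ccl1 (ENSMUSG00000020702.13, 1099-fold higher by counts, 95% interval 197 to 43450) and Ccl9 (ENSMUSG00000019122.8, at least 38.5-fold higher) rose with the largest fitted changes there. Csf1 (ENSMUSG00000014599.10, chromosome 3, 107741048 to 107760469), the growth factor of macrophages, averaged 30.9 ± 13.6 against 0.621 ± 0.0902 CPM (log2 fold change 5.61, SE 0.50, edgeR adjusted p = 5.79e-07). Xcl1 (ENSMUSG00000026573.7, chromosome 1, 164931644 to 164935527), which attracts cross-presenting dendritic cells, averaged 185 ± 63.3 against 2.93 ± 2.11 CPM (log2 fold change 6.0, SE 0.52, edgeR adjusted p = 1.02e-05). Ccl4 (ENSMUSG00000018930.3, log2 fold change 5.08, SE 0.59) and Ccl5 (2.0, SE 0.56) rose too. Macrophage markers summed to 273 ± 34.2 CPM at day 14 and 145 ± 17.6 CPM in effector libraries. After the melanoma subtraction, 10 of 11 cytotoxic genes and 9 of 11 factors were still higher in both tumour groups, all but Gzmf, Ccl3 and Ccl4. Gzmb was not called after the melanoma subtraction, which raised its SE (log2 fold change 3.55, SE 1.69, edgeR adjusted p = 0.102) or in the fit of the compared groups alone (edgeR adjusted p = 0.0517), range over all alternatives 3.84e-05 to 0.102. Gzmb, Ccl3, Ccl4 and Ccl5 had log2 fold changes of 5.64, 8.61, 5.95 and 2.69 without effector replicate 2. Ifng had a log2 fold change of 8.06 without effector replicate 1. Ifng and Xcl1 had log2 fold changes of 9.23 and 6.63 without effector replicate 3. Ccl3 had a log2 fold change of 7.06 (SE 0.45) after the melanoma subtraction. Cx3cr1 was by counts 856-fold (95% interval 153 to 33810) higher without effector replicate 1, 889.8-fold (159.5 to 35170) without effector replicate 3 and at least 312-fold without effector replicate 2. Gzmf was by counts at least 20.7-fold higher without effector replicate 1, at least 21.5-fold without effector replicate 3 and at least 21.4-fold without day 14 replicate 1. Ccl1 was by counts 702-fold (95% interval 126 to 27730) higher without effector replicate 1, 729.8-fold (131 to 28840) without effector replicate 3 and at least 256-fold without effector replicate 2. Ccl9 was by counts at least 24.6-fold higher without effector replicate 1 and at least 25.5-fold without effector replicate 3.

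Cell cycle genes were higher at day 14 than in effector cells. Of 20 mitosis genes 20 rose and 0 fell (20 and 0 adjusted over the list alone, camera adjusted p = 4.08e-05, and adjusted p = 0.424 with an estimated correlation), and of 19 DNA replication genes 19 rose and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 1.57e-08, and adjusted p = 0.165 with an estimated correlation). Mki67 averaged 2284 ± 351 against 228 ± 305 CPM (log2 fold change 3.33, SE 0.99, edgeR adjusted p = 0.0180). The mitotic genes Bub1 (ENSMUSG00000027379.13, log2 fold change 3.83, SE 0.85), Cdk1 (ENSMUSG00000019942.13, log2 fold change 3.74, SE 0.65) and Ccna2 (ENSMUSG00000027715.9, log2 fold change 3.56, SE 1.05) and the replication genes Cdc6 (ENSMUSG00000017499.15, log2 fold change 4.05, SE 0.56), Dtl (ENSMUSG00000037474.13, log2 fold change 4.0, SE 0.33) and Gins2 (ENSMUSG00000031821.11, log2 fold change 3.92, SE 0.23) led. All 20 mitosis and 19 replication genes were still higher in both tumour groups after the melanoma subtraction. Mki67 was not called in the fit of the compared groups alone (edgeR adjusted p = 0.0795), range over all alternatives 0.000110 to 0.0795. Ccna2 was not called in the fit of the compared groups alone (edgeR adjusted p = 0.0889), range over all alternatives 2.14e-05 to 0.0889. Mki67, Bub1, Cdk1, Ccna2 and Cdc6 had log2 fold changes of 5.46, 5.78, 4.99, 6.57 and 5.36 without effector replicate 2.

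Of 16 immediate early and stress genes 15 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 2.43e-06, and adjusted p = 0.0672 with an estimated correlation), with Fosb (ENSMUSG00000003545.3, log2 fold change 8.85, SE 0.51), Fos (ENSMUSG00000021250.13, log2 fold change 8.27, SE 0.48) and Dusp1 (ENSMUSG00000024190.7, log2 fold change 6.30, SE 0.28) highest, and 11 of the 13 higher in both tumour groups remained so after the melanoma subtraction. Of 17 glycolysis genes 14 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 1.03e-05, and adjusted p = 0.216 with an estimated correlation). Of 11 chemokine receptors 6 rose and 3 fell (6 and 3 adjusted over the list alone), of 20 interferon genes 2 rose and 9 fell (2 and 9 adjusted over the list alone) and of 22 ribosomal protein genes 4 rose and 4 fell (3 and 4 adjusted over the list alone), and none of these 3 lists was called. Fos had a log2 fold change of 9.03 without effector replicate 1. Fos and Fosb had log2 fold changes of 7.26 and 8.21 (SEs 0.40 and 0.67) after the melanoma subtraction. In all, 10025 of 16426 genes were called, 5356 higher and 4669 lower, 6197 of them by at least 2-fold.

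**Figure D3:**
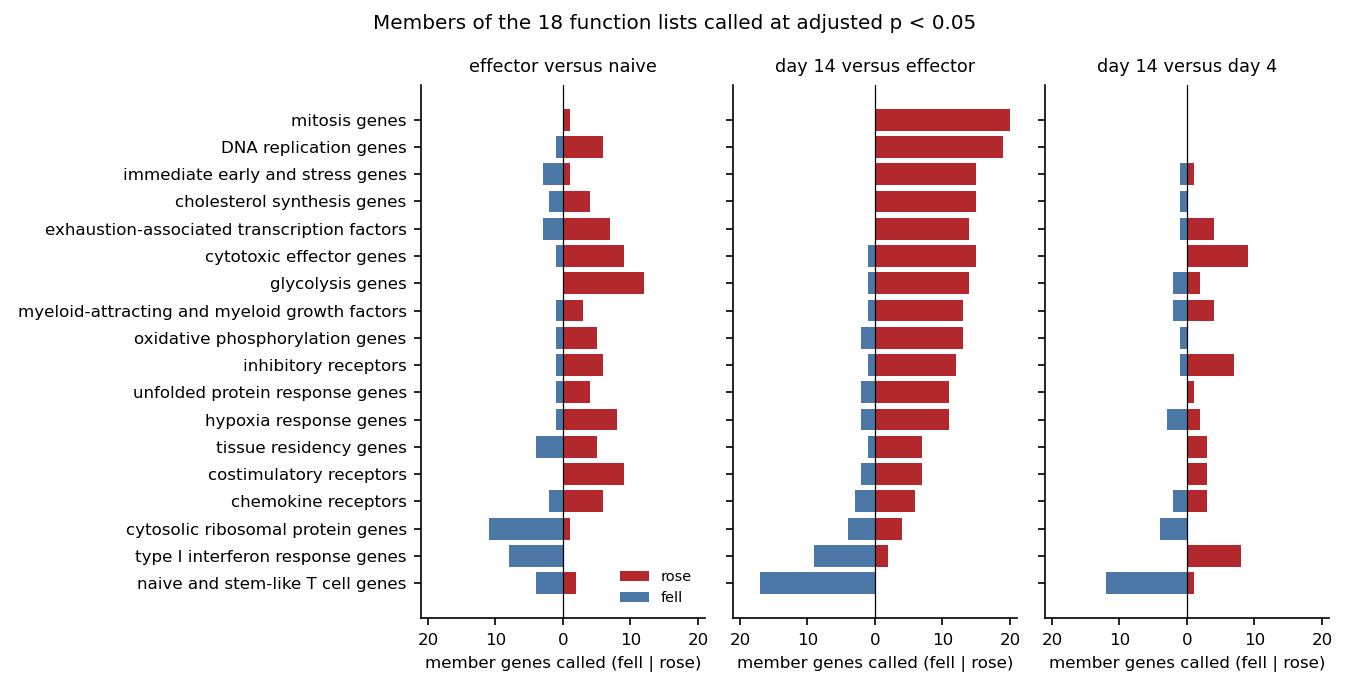
Number of member genes called in each of the 18 function lists in the 3 main contrasts, with those that rose as bars to the right of 0 and those that fell as bars to the left. All 20 mitosis genes rose at day 14 against effector and 0 were called between day 14 and day 4.

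Day 14 and day 4 tumour cells were compared to ask how transcripts differ with time in the tumour. Ccl5 averaged 482 ± 124 CPM at day 14 and 31.3 ± 10.2 CPM at day 4 (15.4-fold higher, log2 fold change 3.94, SE 0.61, edgeR adjusted p = 0.00388). Prdm1 (ENSMUSG00000038151.13), which encodes BLIMP-1, rose from 19.9 ± 15.8 to 207 ± 9.82 CPM (log2 fold change 3.37, SE 0.59, edgeR adjusted p = 0.00688). The chemokine receptor Cxcr6 (ENSMUSG00000048521.8, log2 fold change 3.02, SE 0.35) rose, as did the inhibitory receptor gene Lilr4b (ENSMUSG00000112023.1, log2 fold change 3.01, SE 0.59). Lrrc32 (ENSMUSG00000090958.2, log2 fold change -3.21, SE 0.29), Ccr6 (ENSMUSG00000040899.14, log2 fold change -3.03, SE 0.41), Tnfsf8 (ENSMUSG00000028362.2, log2 fold change -2.50, SE 0.32) and Sspo (ENSMUSG00000029797.13, log2 fold change -2.44, SE 0.37) fell, and Lrrc32 encodes GARP, a docking receptor of latent TGF-beta. Lilr4b was not called without day 4 replicate 1 or 2 (edgeR adjusted p = 0.0588 and 0.0578), range over all alternatives 7.97e-06 to 0.0588. Prdm1 had a log2 fold change of 4.21 without day 4 replicate 3. Cxcr6 had a log2 fold change of 4.88 (SE 1.36) after the melanoma subtraction, which left 647 of its 2747 counts at day 4. Ccl5 kept 0 of its 1416 counts at day 4 after the melanoma subtraction, so the fitted log2 fold change (15.49) depends on the prior count. Lilr4b kept 0 of its 1487 counts at day 4 after the melanoma subtraction, so the fitted log2 fold change (14.05) depends on the prior count.

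Naive and stem-like genes were lower at day 14 than at day 4. Of 18 genes 1 rose and 12 fell (1 and 13 adjusted over the list alone, camera adjusted p = 1.57e-08, and adjusted p = 0.164 with an estimated correlation). Dapl1 (ENSMUSG00000026989.5, log2 fold change -3.0, SE 0.42) and Satb1 (ENSMUSG00000023927.15, log2 fold change -2.42, SE 0.26) were among the largest falls, Klf2 (ENSMUSG00000055148.7, log2 fold change 1.10, SE 0.31) was the 1 that rose, and Tcf7 averaged 62.2 ± 36.5 against 252 ± 8.58 CPM (log2 fold change -2.02, SE 0.33, edgeR adjusted p = 0.00417). Of 14 inhibitory receptors 7 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.00101, and adjusted p = 0.165 with an estimated correlation), with Cd244a (log2 fold change 2.83, SE 0.51), Entpd1 (log2 fold change 2.53, SE 0.38) and Cd200r1 (ENSMUSG00000022667.18, log2 fold change 2.50, SE 0.36) highest and Btla (log2 fold change -1.81, SE 0.18) as the 1 that fell. Pdcd1 averaged 697 ± 55.6 against 378 ± 28.5 CPM (log2 fold change 0.88, SE 0.21, edgeR adjusted p = 0.0187). Not called were Havcr2 (log2 fold change 2.78, SE 0.78, edgeR adjusted p = 0.0551) and Lag3 (log2 fold change 0.80, SE 0.35, edgeR adjusted p = 0.192). Melanoma markers summed to 1130 ± 224 CPM at day 4 and 1145 ± 807 CPM at day 14. Klf2 was not called without day 4 replicate 2 or 3 or day 14 replicate 1, 2 or 3 (edgeR adjusted p = 0.0627 to 0.128) or in the fit of the compared groups alone (edgeR adjusted p = 0.122), range over all alternatives 0.000112 to 0.128. Pdcd1 was not called without day 4 replicate 1 or 2 or day 14 replicate 2 or 3 (edgeR adjusted p = 0.0533 to 0.0798) or with no filter on low counts (edgeR adjusted p = 0.0648), range over all alternatives 0.000102 to 0.0798. Havcr2 was called without effector replicate 1, 2 or 3 (edgeR adjusted p = 0.0460, 0.000544 and 0.0347), with the filter of 50 counts (edgeR adjusted p = 0.0431), with protein-coding genes alone (edgeR adjusted p = 0.0477), by DESeq2 (DESeq2 adjusted p = 0.0113) and in the fit of the compared groups alone (edgeR adjusted p = 0.00681), range over all alternatives 0.000544 to 0.177. Lag3 was called without effector replicate 1 or 3 (edgeR adjusted p = 0.0332 and 0.0322) and in the fit of the compared groups alone (edgeR adjusted p = 0.00702), range over all alternatives 0.00702 to 0.431. Dapl1 and Tcf7 had log2 fold changes of -3.76 and -2.63 without day 14 replicate 3. Satb1, Cd244a, Cd200r1 and Havcr2 had log2 fold changes of -3.18, 4.12, 3.82 and 4.28 (SEs 0.49, 0.75, 0.80 and 1.63) after the melanoma subtraction. Entpd1 kept 7 of its 543 counts at day 4 after the melanoma subtraction, so the fitted log2 fold change (8.15) rests on a group with few counts left.

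Of 18 cytotoxic genes 9 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 3.78e-05, and adjusted p = 0.209 with an estimated correlation), with Gzmk (log2 fold change 2.72, SE 0.46), Prf1 (log2 fold change 2.41, SE 0.24) and Fasl (log2 fold change 2.37, SE 0.33) highest, a granzyme, perforin and Fas ligand. Ifng rose (log2 fold change 1.03, SE 0.24, edgeR adjusted p = 0.0135), and Gzmb was not called (log2 fold change 1.86, SE 0.83, edgeR adjusted p = 0.215). Of 12 tissue residency genes 3 rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.00335, and adjusted p = 0.165 with an estimated correlation), namely Cxcr6, Runx3 (ENSMUSG00000070691.10) and Rgs1. Runx3 and Rgs1 had log2 fold changes of 1.17 and 2.11 (SEs 0.14 and 0.19). Of 15 transcription factors 4 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.0434, and adjusted p = 0.297 with an estimated correlation), with Id2 (ENSMUSG00000020644.9, log2 fold change 2.07, SE 0.23) and Tox2 (log2 fold change 1.74, SE 0.43) beside Prdm1. Tox rose (log2 fold change 0.96, SE 0.12, edgeR adjusted p = 6.02e-05), and Ikzf2 (ENSMUSG00000025997.13, log2 fold change -1.32, SE 0.28), which encodes Helios, fell. Of 10 costimulatory receptors 3 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0148, and adjusted p = 0.209 with an estimated correlation), namely Slamf1 (ENSMUSG00000015316.11, log2 fold change 0.77, SE 0.16), Icos (log2 fold change 0.64, SE 0.12) and Tnfrsf1b (log2 fold change 0.58, SE 0.13). Fibroblast markers, another tumour signal, summed to 237 ± 67.7 CPM at day 4 and 222 ± 139 CPM at day 14, with melanoma markers as above. Ifng was not called without day 4 replicate 1 or 2 or day 14 replicate 1 or 2 (edgeR adjusted p = 0.0517 to 0.0690), range over all alternatives 2.29e-10 to 0.0690. Gzmb was called without effector replicate 2 (edgeR adjusted p = 0.0134) and in the fit of the compared groups alone (edgeR adjusted p = 0.00109), range over all alternatives 0.00109 to 0.416. Tox2 was not called without day 4 replicate 1 or 2 or day 14 replicate 2 (edgeR adjusted p = 0.0729, 0.0636 and 0.119), range over all alternatives 0.000281 to 0.119. Ikzf2 was not called without day 14 replicate 1 (edgeR adjusted p = 0.0575), range over all alternatives 1.58e-05 to 0.0575. Prf1, Ifng, Gzmb, Rgs1 and Id2 had log2 fold changes of 4.96, 1.87, 3.58, 3.20 and 3.52 (SEs 1.16, 0.35, 1.69, 0.42 and 0.38) after the melanoma subtraction.

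Of 20 type I interferon genes 8 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 2.32e-05, and adjusted p = 0.332 with an estimated correlation), with Ifit3 (ENSMUSG00000074896.3, log2 fold change 1.84, SE 0.47), Zbp1 (ENSMUSG00000027514.14, log2 fold change 1.42, SE 0.33) and Oas1a (ENSMUSG00000052776.10, log2 fold change 1.32, SE 0.33) highest. Of 15 myeloid-attracting factors 4 rose and 2 fell (4 and 2 adjusted over the list alone) and the list, which follows the theme of the series, was not called. Ccl4 averaged 51.5 ± 15.4 against 11.5 ± 6.05 CPM (log2 fold change 2.16, SE 0.48, edgeR adjusted p = 0.0150). Ccl3 rose (log2 fold change 2.37, SE 0.39, edgeR adjusted p = 0.00435), Csf1 was not called (log2 fold change 0.80, SE 0.36, edgeR adjusted p = 0.185) and Xcl1 was not called (log2 fold change -0.92, SE 0.38, edgeR adjusted p = 0.176). Melanoma marker sums are as above. Ifit3 was not called without day 4 replicate 1 or 2 or day 14 replicate 1 or 3 (edgeR adjusted p = 0.0805 to 0.125) or with no filter on low counts (edgeR adjusted p = 0.0880), range over all alternatives 0.00133 to 0.125. Zbp1 was not called without day 4 replicate 1 or 2 or day 14 replicate 1 or 3 (edgeR adjusted p = 0.0600 to 0.0946), range over all alternatives 0.000233 to 0.0946. Oas1a was not called without day 4 replicate 1 or 2 or day 14 replicate 1 (edgeR adjusted p = 0.0550, 0.0755 and 0.0637), range over all alternatives 1.56e-07 to 0.0755. Ccl4 was not called without day 4 replicate 1 or 2 or day 14 replicate 1 or 2 (edgeR adjusted p = 0.0511 to 0.0720), range over all alternatives 0.00334 to 0.0720. Csf1 was called without day 14 replicate 3 (edgeR adjusted p = 0.0306) and with no filter on low counts (edgeR adjusted p = 0.00496), range over all alternatives 0.00496 to 0.570. Xcl1 was called without effector replicate 1 (edgeR adjusted p = 0.0408), range over all alternatives 0.0408 to 0.396. Ifit3, Oas1a and Ccl4 had log2 fold changes of 3.52, 3.03 and 4.06 (SEs 0.96, 0.76 and 1.18) after the melanoma subtraction. Ccl3 kept 0 of its 1809 counts at day 4 after the melanoma subtraction, so the fitted log2 fold change (13.65) depends on the prior count.

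Between the 2 times, edgeR and DESeq2 called 0 of 20 mitosis and 0 of 19 replication genes. At an unadjusted p under 0.05 only 2 replication genes changed, both lower. Mki67 averaged 2284 ± 351 CPM at day 14 and 2165 ± 66.5 CPM at day 4 (log2 fold change 0.08, SE 0.90, edgeR adjusted p = 0.981). The SE takes in effector replicate 2, which lay apart, so these tests could miss changes. Of 22 ribosomal protein genes 0 rose and 4 fell (0 and 9 adjusted over the list alone, camera adjusted p = 0.000506, and adjusted p = 0.451 with an estimated correlation), and of 21 oxidative phosphorylation genes 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.0353, and adjusted p = 0.493 with an estimated correlation). The lists of chemokine receptors (3 rose and 2 fell of 11), glycolysis (2 rose and 2 fell of 17), hypoxia (2 rose and 3 fell of 16), cholesterol synthesis (0 rose and 1 fell of 20), immediate early genes (1 rose and 1 fell of 16) and the unfolded protein response (1 rose and 0 fell of 14) were not called. In all, 1984 of 16426 genes were called, 1178 higher and 806 lower, 732 of them by at least 2-fold. Without day 14 replicate 2 the count was 1283, which is more than 1.5 times lower.

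In the further contrasts, day 4 cells against naive cells had 10221 genes called (5493 higher and 4728 lower), day 14 against naive 10202 (5527 and 4675) and day 4 against effector 10174 (5372 and 4802), of 16426 each. Against naive cells at day 4, Bhlhe40 (log2 fold change 10.14, SE 0.34) and Dct (log2 fold change 9.21, SE 0.76) rose most and Ccr9 (log2 fold change -7.70, SE 0.82) and Oas2 (log2 fold change -6.41, SE 0.34) fell most by the rule. Against naive cells at day 14, Havcr2 (log2 fold change 10.75, SE 1.27) and Rgs16 (log2 fold change 10.37, SE 0.19) rose most and Ccr9 (log2 fold change -8.78, SE 0.89) was among those that fell most. Against effector cells at day 4, Dct (log2 fold change 9.75, SE 0.79) and Dusp4 (ENSMUSG00000031530.6, log2 fold change 8.40, SE 0.18) rose most, the latter a MAP kinase phosphatase, and Ifit1bl1 (ENSMUSG00000079339.7, log2 fold change -5.96, SE 0.17) and S1pr1 (ENSMUSG00000045092.8, log2 fold change -5.48, SE 0.56) fell most, the latter a receptor for exit from lymph nodes. Dct at day 4 against naive had a log2 fold change of -0.07 (SE 2.03) after the melanoma subtraction and was not called (edgeR adjusted p = 0.980, range over all alternatives 1.12e-46 to 0.980). Dct at day 4 against naive had a log2 fold change of 10.09 without naive replicate 2. Rgs16 at day 14 against naive had a log2 fold change of 10.99 without naive replicate 1. The melanoma subtraction uses Dct and cannot test it. Dct at day 4 against effector was not called there (log2 fold change 0.48, SE 2.10, edgeR adjusted p = 0.855). Its adjusted p ranged from 1.26e-49 to 0.855 over all alternatives. Camera called 16, 18 and 13 of the 18 function lists in these contrasts, beside 9, 14 and 9 in the main ones. With an estimated correlation 0 of 18 were called in each of the 6 contrasts by camera, with 8, 10, 3, 2, 6 and 3 at an unadjusted p under 0.05, and fry called 17, 18, 17, 11, 16 and 8. The signs of median, mean and test differed in 6 of 108 function list tests and 7 of 54 marker list tests, 0 of them called.

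Both tumour groups shared changes against both other groups. The 4 contrasts together gave 3724 genes higher and 2931 lower in both tumour groups than in naive and effector cells, where independent lists would share 197.1 and 111.8. In 20 simulations with no group differing, 0 genes met this, but no contrast called over 3 genes there, so they say little about shared controls. Part of the excess can come from the shared controls, since 3 controls per group cannot be split. By the rule the highest were Dct, Rgs16, Pdcd1, Nr4a2, Nr4a3, Xcl1, Tnfrsf9 and Gpnmb (ENSMUSG00000029816.10), and among the lowest were S1pr1, Art2b (ENSMUSG00000030651.5) and Treml2 (ENSMUSG00000071068.7). Gpnmb is a melanoma marker like Dct, with a log2 fold change of 5.86 (SE 0.69) at day 14 against effector. Art2b and Treml2 had log2 fold changes of -4.28 (SE 0.29) and -6.02 (SE 0.45) in that contrast. The melanoma subtraction uses Gpnmb and cannot test it. Gpnmb was not called there (log2 fold change -1.79, SE 1.37, edgeR adjusted p = 0.284), range over all alternatives 2.79e-21 to 0.284. Gpnmb had a log2 fold change of 5.16 without day 14 replicate 1.

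Markers of other cell types were measured in all groups. The 10 melanoma markers summed to 30.8 ± 3.69, 42.7 ± 1.31, 1130 ± 224 and 1145 ± 807 CPM in naive, effector, day 4 and day 14 libraries, and all 10 rose in both tumour groups against both other groups (camera adjusted p = 3.68e-05, and adjusted p = 0.602 with an estimated correlation at day 14 against effector). Fibroblast markers summed to 4.14 ± 0.0740, 1.43 ± 0.444, 237 ± 67.7 and 222 ± 139 CPM in the same order, led by Fn1 (ENSMUSG00000026193.15), and 8 of 8 rose at day 14 against effector (camera adjusted p = 0.0149, and adjusted p = 0.602 with an estimated correlation). Macrophage markers, of which Ctss (ENSMUSG00000038642.10) was the most abundant, summed to 140.1 ± 13.1, 145 ± 17.6, 282 ± 59.3 and 273 ± 34.2 CPM, and 13 rose and 1 fell of 18 at day 14 against effector (camera adjusted p = 0.00435, and adjusted p = 0.602 with an estimated correlation). Dendritic cell and MHC class II markers summed to 23.3 ± 12.8, 15.7 ± 7.15, 131 ± 18.1 and 183 ± 25.1 CPM, led by Cd74 (ENSMUSG00000024610.15), and 5 of 7 rose (5 and 0 adjusted over the list alone). B cell markers summed to 931 ± 79.6, 1334 ± 92.4, 379.7 ± 17 and 189.6 ± 96.1 CPM, nearly all of it Ighm (ENSMUSG00000076617.9), and 2 rose and 3 fell of 8. Endothelial markers summed to 185 ± 10.9, 181 ± 4.96, 78.3 ± 11.7 and 55.4 ± 10.1 CPM, mostly Pecam1 (ENSMUSG00000020717.19), which naive T cells also express, and 1 rose and 1 fell of 2.

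NK cell markers summed to 0.647 ± 0.368, 3.39 ± 2.32, 12.9 ± 1.45 and 7.08 ± 2.56 CPM, led by Klre1 (ENSMUSG00000050241.8), and 1 rose and 0 fell of 2 at day 14 against effector. CD4 T cell and Treg markers, led by Ikzf4 (ENSMUSG00000002578.18), summed to 21.3 ± 5.31, 46.2 ± 5.01, 32.9 ± 3.38 and 44.2 ± 9.67 CPM, and 1 rose and 0 fell of 6. Erythroid markers, led by Hbb-bs (ENSMUSG00000052305.6), summed to 18.7 ± 12, 2.39 ± 0.435, 5.84 ± 4.78 and 9.60 ± 6.08 CPM, and 3 rose and 0 fell of 4. Neutrophil markers, led by Csf3r (ENSMUSG00000028859.14), summed to 0.995 ± 0.600, 0.0287 ± 0.0496, 0.588 ± 0.729 and 0.145 ± 0.152 CPM, and 0 of 8 passed the count filter, so no test was made. Between day 14 and day 4, edgeR called 0 of the 18 macrophage, 7 dendritic cell, 10 melanoma, 8 fibroblast, 2 NK cell, 6 CD4 T cell and Treg and 4 erythroid markers. At an unadjusted p under 0.05 the counts in that order were 0, 3, 0, 1, 1, 1 and 0, and DESeq2 called 0, 1, 0, 0, 1, 0 and 0. For B cell and endothelial markers, 0 rose and 2 fell of 8 and 0 rose and 1 fell of 2.

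**Figure D4:**
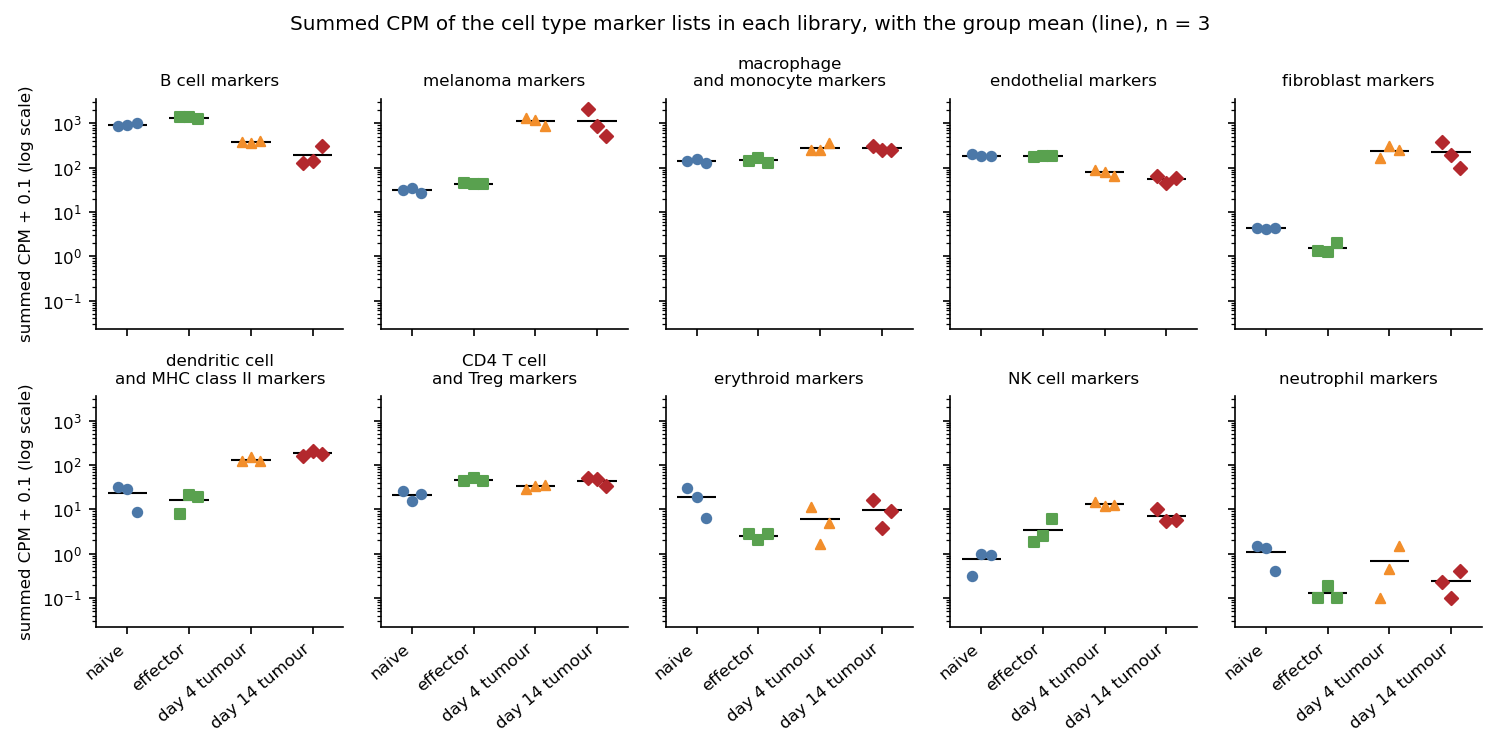
Summed CPM plus 0.1, on a log axis, of each marker list, with 1 point per library, 3 libraries per group and a line at the group mean. Melanoma markers sum to between 513 and 2054 CPM at day 14 and to at most 44.1 CPM in naive and effector libraries.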

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

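The 5 genes here were picked out after their values were seen, by a rule set in advance that compares the effect at day 4 with the effect at day 14 against the same reference. In each gene of a fixed list named here, both effects passed the test with opposite signs, and the difference between the times passed it too. Of all genes tested, 43 behaved so against naive cells (2 of them in the fixed lists) and 51 against effector cells (5 in the lists). For Ccl5, log2 fold changes against effector cells were -1.94 at day 4 and 2.0 at day 14, a difference of 3.94 (SE 0.61, edgeR adjusted p = 0.00388). Ccl5 at day 4 against effector was not called without day 4 replicate 1 or 2 (edgeR adjusted p = 0.0596 and 0.0639), range over all alternatives 0.000353 to 0.0639. Ccl5 at day 4 against effector had a log2 fold change of -1.26 without effector replicate 2. Ccl5 kept 0 of its 1416 counts at day 4 after the melanoma subtraction, so the fitted log2 fold change at day 4 against effector (-13.69) depends on the prior count. Ccl5 at day 14 against effector had a log2 fold change of 2.69 without effector replicate 2.

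For Cxcr6, log2 fold changes against effector cells were -1.34 at day 4 and 1.67 at day 14 (SEs 0.33 and 0.33), a difference of 3.02 (SE 0.35, edgeR adjusted p = 0.000634). Cxcr6 at day 4 against effector was not called after the melanoma subtraction, which took its fold change further from 0 and raised its SE (log2 fold change -3.30, SE 1.29, edgeR adjusted p = 0.0523), range over all alternatives 0.000426 to 0.0523. Cxcr6 at day 14 against effector was not called after the melanoma subtraction, which raised its SE (log2 fold change 1.58, SE 1.16, edgeR adjusted p = 0.270), range over all alternatives 2.97e-06 to 0.270.

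The lymph node homing receptor Ccr7 (ENSMUSG00000037944.8) and Dapl1 went the other way. For Ccr7, log2 fold changes against effector cells were 1.46 at day 4 and -0.91 at day 14, and 1.59 and -0.77 against naive cells, a difference of -2.37 (SE 0.24, edgeR adjusted p = 0.000128). For Dapl1, log2 fold changes against effector cells were 1.18 at day 4 and -1.82 at day 14, a difference of -3.0 (SE 0.42, edgeR adjusted p = 0.000954). For Runx3, a factor of cytotoxic and resident T cells, log2 fold changes against naive cells were -0.56 at day 4 and 0.61 at day 14, a difference of 1.17 (SE 0.14, edgeR adjusted p = 8.88e-05). Dapl1 at day 4 against effector was not called without effector replicate 1 or 2 or day 4 replicate 3 (edgeR adjusted p = 0.0570, 0.0615 and 0.0507) or with no filter on low counts (edgeR adjusted p = 0.0567), range over all alternatives 0.000159 to 0.0615. Dapl1 at day 14 against effector had a log2 fold change of -2.57 without day 14 replicate 3. Ccr7 at day 14 against effector had a log2 fold change of -1.64 (SE 0.37) after the melanoma subtraction. Dapl1 at day 14 against day 4 had a log2 fold change of -3.76 without day 14 replicate 3. Ccr7 at day 14 against day 4 had a log2 fold change of -3.09 (SE 0.38) after the melanoma subtraction. Ccr7 at day 14 against naive had a log2 fold change of -1.51 (SE 0.36) after the melanoma subtraction. Groups of 3 libraries were not tested for outlying samples.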

How the results depend on the processing

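The melanoma subtraction and its results were chosen after the values were seen, and the other alternatives were listed before. Under other scalings, filters, gene sets, DESeq2, fits of the compared groups alone and the replicate block, each count of genes that differed stayed within 1.5 times its value. DESeq2 called 4388, 10402 and 2355 genes in the 3 main contrasts and 10541, 10603 and 10500 in the further ones. Its gene set may differ from that of edgeR. After the melanoma subtraction the counts were 4050, 9614 and 2685 for the main contrasts and 9897, 9854 and 9876 for the further ones.

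With 1 library left out, the counts ranged from 3086 to 4125 for effector versus naive, from 9313 to 10196 for day 14 versus effector and from 1283 to 2206 for day 14 versus day 4. The lowest of the last came without day 14 replicate 2, and the cause was not tested. Ranges were 9542 to 10568 for day 4 versus naive, 9511 to 10562 for day 14 versus naive, 9468 to 10377 for day 4 versus effector and 12016 to 12366 for the test over 4 groups. Genes higher in both tumour groups ranged from 3585 to 3738 and genes lower from 2643 to 2858. A group with a library left out holds 2 libraries, whose spread is shared with the other groups.

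Camera with an estimated correlation called 0 lists in each of the 6 contrasts, against 9, 14, 9, 16, 18 and 13 with the preset one. Another split gave about as many preset calls (below), so these do not single out the real grouping. The log2 difference of melanoma markers between day 4 and naive libraries was 5.18 by summed CPM and 4.45 by medians over markers, where the most abundant marker has less weight.

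Same-numbered libraries did not deviate together. Their 18 correlations ranged from -0.09 to 0.10, so replicate numbers were not taken to pair samples. With the replicate number as a block the counts were 3933, 9887 and 1931 for the main contrasts, 10054, 10046 and 10011 for the further ones and 12054 over the 4 groups. Among named genes the call ended for 1, Ccnb1 in effector versus naive (log2 fold change 2.25, SE 0.68, edgeR adjusted p = 0.0557, range over all alternatives 0.00299 to 0.116).

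Of 172 results for named genes, 137 kept their call under each alternative. With 1 library left out, 15 lost their call at least once and 7 gained one. The fits of the compared groups alone ended 7 calls and added 4, the fit with no filter ended 4 and added 1, and the melanoma subtraction ended 9 and 2 more whose sign turned, and added 0. DESeq2 ended 0 and added 2, the filter of 50 counts and protein-coding genes alone added 1 each, and total counts ended 1. Dct turned to -0.072 in day 4 against naive after the melanoma subtraction. Gpnmb turned to -1.79 in day 14 against effector after the melanoma subtraction.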

Other observations

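All tests of explanations here were chosen after the results were seen, except the melanoma subtraction for the myeloid-attracting factors, whose bounds were written before its result. Some metabolic genes were higher in both tumour groups. Of 20 cholesterol synthesis genes, at day 14 against effector 15 rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 0.000134, and adjusted p = 0.217 with an estimated correlation), with Idi1 (ENSMUSG00000058258.14, log2 fold change 2.81, SE 0.22) and Cyp51 (ENSMUSG00000001467.5, log2 fold change 2.62, SE 0.29), both enzymes of the pathway, among the highest. Of 21 oxidative phosphorylation genes in the same contrast 13 rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.00790, and adjusted p = 0.416 with an estimated correlation), with Cycs (ENSMUSG00000063694.5, log2 fold change 1.78, SE 0.14), Cox7a2 (ENSMUSG00000032330.7, log2 fold change 1.41, SE 0.12) and Ndufa4 (ENSMUSG00000029632.7, log2 fold change 1.35, SE 0.13). Of 17 glycolysis genes all rose in both tumour groups against naive cells (camera adjusted p = 1.88e-08, and adjusted p = 0.165 with an estimated correlation at day 14), with a log2 fold change of 6.10 (SE 0.30) for Hk2. Of 16 hypoxia response genes 11 rose and 2 fell at day 14 against effector (11 and 2 adjusted over the list alone) and the list was not called. Car9 (ENSMUSG00000028463.14, log2 fold change 3.89, SE 0.53) and Pdk1 (ENSMUSG00000006494.11, log2 fold change -2.47, SE 0.14) went opposite ways there. Higher in both tumour groups were 13 of 20 cholesterol, 13 of 21 oxidative phosphorylation, 13 of 17 glycolysis and 9 of 16 hypoxia genes. The melanoma subtraction ended this for Bnip3, Ndrg1 and Car9 alone. Car9 was not called after the melanoma subtraction, which lowered its fold change and raised its SE (log2 fold change 1.84, SE 1.49, edgeR adjusted p = 0.308), range over all alternatives 1.15e-30 to 0.308. Car9 had a log2 fold change of 3.21 without day 14 replicate 1.

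Among 14 unfolded protein response genes 11 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.00621, and adjusted p = 0.223 with an estimated correlation) at day 14 against effector. The chaperone Hspa5 (ENSMUSG00000026864.13, log2 fold change 2.21, SE 0.14) and the amino acid enzyme Asns (ENSMUSG00000029752.12, log2 fold change 2.66, SE 0.34) rose, while the stress-induced pseudokinase Trib3 (ENSMUSG00000032715.9, log2 fold change -5.08, SE 0.51) and Ddit3 (ENSMUSG00000025408.15, log2 fold change -1.34, SE 0.23) fell. Type I interferon genes were lower in both tumour groups than in naive cells, where 0 rose and 15 fell (0 and 16 adjusted over the list alone, camera adjusted p = 1.12e-05, and adjusted p = 0.312 with an estimated correlation) at day 4 and 1 rose and 12 fell (1 and 12 adjusted over the list alone, camera adjusted p = 0.00102, and adjusted p = 0.445 with an estimated correlation) at day 14. Usp18, which restrains interferon signals, had a log2 fold change of -3.65 (SE 0.24) at day 14 against naive. Melanoma marker sums of these libraries follow below. Asns had a log2 fold change of 3.31 without effector replicate 3.

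Melanoma marker transcripts stood at 1130 ± 224 CPM at day 4 and 1145 ± 807 CPM at day 14, though CD44-positive OT-I cells had been sorted. The 10 markers moved together over the 6 tumour libraries, with a median SD of 0.229 for their log2 ratio to the other 9 markers against 0.654 for their own log2 CPM, which is consistent with melanoma RNA in the sorted samples. As the source of the 3724 genes higher in both tumour groups as a set, such RNA cannot be told apart. The median within-group SD of their log2 ratio to the marker sum was 0.766, above the highest marker (0.672, S100b), with 1029 of them (27.6%) at or under that marker, but 0.434 and 0.584, under the highest marker (0.755 and 0.681), without day 14 replicate 1 or 3. The subtraction came first and left 2974 (79.9%) of these genes, between the bounds set for it, so by it alone the source cannot be told apart. Tumour-derived signals that change T cell transcripts remain an untested biological explanation.

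Myeloid-attracting factors were higher in the tumour libraries. RNA of macrophages in fixed proportion to Lyz2, C1qa, C1qb and C1qc is argued against for the 10 members other than Ccl2 as a set. The median within-group SD of their log2 ratio to these markers together was 1.061, above the highest marker against the other 3 (0.648). It was lowest without day 4 replicate 3 (0.719 against 0.569, 7 of 10 above). Ccl2, at most 3.27 CPM, moved with them (SD 0.196), which is consistent with such RNA. Melanoma RNA cannot be told apart for the members other than Ccl3, whose median SD against the melanoma marker sum was 0.797, above the highest marker (0.672), but 0.733 and 0.619, under it (0.755 and 0.681), without day 14 replicate 1 or 3, nor for Ccl3 (0.632), between the bounds set. The subtraction kept 9 of 11 members. It moved Ccl3 at day 4 against effector from 5.52 (SE 0.58) to -6.59 (SE 1.57, with 0 of 1809 counts left at day 4). Ccl4 moved from 2.92 (SE 0.58) to 0.60 (SE 1.34, edgeR adjusted p = 0.719, with 96 of 522 left) and was not called. Expression by the T cells in the tumours, or by macrophages in varying states, remains an untested biological explanation.

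The effector libraries held few cytotoxic and mitosis transcripts, and replicate 2 lay apart with 189 CPM of Gzmb and 579.6 CPM of Mki67. Naive cells under the effector label are argued against, since 5 of 24 inhibitory and costimulatory receptor genes (Ctla4, Lag3, Tigit, Klrc1 and Entpd1) were at least 4 times as high in every effector library as in the highest naive library, and 0 were as much lower. A share of naive cells was not tested. Tumour RNA mixed into replicate 2 is argued against by a median share of 3.30% (quartiles 0.17% and 13.7%) of the tumour level over 154 other genes higher in both tumour groups, against 24.5% over mitosis genes. A culture whose cells were still dividing could account for replicate 2, and this was not tested.

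Other splits of the same libraries were fitted as well. Of 100 splits of all libraries, only the real one reached 12283 genes over the 4 groups (highest other 348). The same held for genes higher (3724) and lower (2931) in both tumour groups (highest other 0 each). Libraries were shuffled, so chance between animals or cultures was untested. For pairs of groups there are 10 splits, too few for a share under 0.05. Fitted on the 2 groups, the real splits gave 3826, 8982 and 2132 genes in the main contrasts and 9805, 9573 and 9396 for day 4 versus naive, day 14 versus naive and day 4 versus effector, with 0 as the highest other in each. Lists called were 9, 15, 7, 16, 18 and 13 in that order, with 8, 14, 7, 15, 15 and 13 as the highest other. The number of splits with a result as large was 1 for each of these, except 2 for the lists between day 14 and day 4 and between day 4 and effector.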
